A study of Mus musculus with 4 samples.

How the data were processed

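Total RNA from the colonic mucosa of C57BL/6 mice at postnatal day 90 (P90) and postnatal day 30 (P30) was compared on 4 two-colour oligonucleotide arrays, called a, b, e and k after the labels. Per the labels' protocols, the mucosa was scraped off and frozen, RNA was purified on columns, and each array received 1 P90 and 1 P30 RNA labelled with the opposite dyes. P90 was labelled with Cy3 on arrays a, b and k and with Cy5 on array e, so array e is the dye swap. The labels call the 4 comparisons independent and name each RNA by the age of an animal, without saying whether an animal was used once; the p-values therefore measure the spread between these 4 pairs, part of which may be technical. All 4 arrays lay on 1 slide and were scanned on 1 day, so no batch was available to test.

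The deposited scanner files hold spot intensity on a linear scale, as the median brightness of the spot and of its local background in each channel, per the file headers before any normalization. The deposited processed signals had been background-subtracted and scaled by 1 linear factor per dye with no intensity-dependent correction, and the deposited log10 ratio is Cy5 over Cy3 of those signals, per the file headers. The software is Agilent Feature Extraction, version 10.5.1.1 per the file headers and version 8.5.1.1 per the submitters' processing notes, and the protocol named in the headers is one for genomic hybridisation. The series' own value table was found to hold log2 ratios of P90 over P30: it matched the authors' deposited log ratio, turned from log10 to log2 with the sign changed on arrays a, b and k, within 0.01 for 80.0% of probes on array a, 87.0% on b, 86.5% on e and 80.5% on k. Its column medians were 0.21 for array a, -0.17 for b, 0.049 for e and 0.17 for k over all gene probes, and -0.067, -0.071, 0.030 and -0.036 over the probes tested here. The outlier, background and saturation marks per spot, of no unit of their own (other), were taken from the deposited scanner files.

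Each array had 45018 spots, of which 43379 were gene spots for 41174 distinct probes. The scanner files name probes by accession only; 25097 probes were named through RefSeq accessions of assembly GRCm38.p6 and 16077 kept the accession of the array's design. The design's own positions belong to another build, so no coordinates are given. Median signals were used because the files used here hold no mean signal, which the test design had assumed. Background was corrected with normexp and an offset of 50, followed by loess within each array with a span of 0.3 and control spots at zero weight, in limma 3.58.1 under R 4.3.3. Spots marked as outliers were left out (127 to 156 gene spots per array), and saturated spots were kept. Every ratio was turned to log2 P90 over P30. Probes well above background in the P90 channel on at least 3 arrays or in the P30 channel on at least 3 arrays were kept (27055 probes, 65.7%), spots of 1 probe were averaged, and the probe with the highest mean intensity stood for its gene. This left 20825 genes and transcripts, of which 13912 had a symbol; 4633 genes had more than 1 kept probe.

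The mean log2 ratio of each gene was tested against 0 with limma's lmFit and eBayes over the 4 arrays, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists (34, for cell types, pathways and tissues that could be admixed, with 603 of 679 members measured) were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were alternatives. The lists shared no members except for 2 genes shared between the goblet cell and mucosal defence lists. Camera compares a list with the remaining genes, and fry tests whether a list's genes move one way on balance. Genes named in the text follow a rule fixed before the data were examined: the 12 largest changes per direction among genes past the test, or, as none passed, the 8 with the smallest p per direction; in each list up to 4 members past the test or else the 2 of highest intensity; and the sex-linked transcripts. Genes saturated on every array in both channels, or in the dimmer one, or on 3 arrays in a channel, are given without values. Further genes were chosen after their values were seen: those with the same direction on all 4 arrays and the largest smallest change, the 4 largest changes in each list that shifted, genes past the test within their own list, and the Cyp3a family. A second adipocyte list and a calcium uptake list were added after the main results were seen but before the values of their members were looked at, except for Trpv6 and S100g; Cebpa was taken off the former after its values had been seen. Some genes that the rule names are not reported here.

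The fits were tested on simulated data with the spread of the real 20815 genes measured on all arrays. Of genes given a 2-fold change 29.8% were called, and of genes given a 4-fold change 72.8%, with 4.15 false calls per run on average. Each simulated gene took the SD of its real array values as its true SD, and 100 genes of each size were changed per run. These shares hold for that setting and do not give the power of the test on the real genes. Camera at the preset correlation found 20 of 20 lists of 25 genes shifted by 0.5, at an unadjusted p below 0.05. Simulated genes were drawn independently, whereas the real lists had a median estimated correlation of 0.215. The simulation therefore does not test list calls among correlated genes. Alternatives covered background correction (processed signals, none, an offset of 16), normalization (median centring, deposited log ratios, scaling between arrays, the series' value table), the filter on dim probes (none, or both channels on all arrays), the mean of a gene's probes, a dye term, array weights, a variance trend, the sign of array e, the threshold, and each array left out in turn. Alternatives added after seeing the data turned the sign of array b, left out arrays b and e together, and left out probes saturated on at least 2 arrays. Leaving array e unturned, or turning array b, reads that array against its labelled dyes. This weakens a shift that all arrays share, so a call lost there is partly by construction. Plots were drawn with matplotlib 3.10.9.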

Results

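Gene expression in the colonic mucosa of young adult mice (90 days) was measured against that of juvenile mice (30 days) on 4 arrays, which the labels call independent comparisons, array e with the dyes exchanged. The series asks which transcripts differ between the 2 ages. The share of gene spots well above background in the P90 channel was 55.6% on array a, 69.3% on b, 65.4% on e and 57.3% on k, and in the P30 channel it was 71.0%, 66.6%, 64.6% and 69.6%. The median P90 signal was 72.0 on array a against a local background of 42, and 114 on array b against the same background of 42. With 4 arrays, the number of pairs limits the precision of every value below.

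Between the ages, Cyp3a44, a cytochrome P450 of the drug-metabolizing Cyp3a family, had the smallest p of all genes, with a log2 P90/P30 of 3.34 ± 0.85 (SD, n = 4) and values from 2.12 to 3.97 on the single arrays. Medians below 0 on every array were found for the interferon response list, with -0.94 over 28 genes, and for the cell cycle list, with -0.53 over 27 genes, and also for the Hox list, which was not called (median -0.15, 23 genes). Extracellular matrix genes had a median of -0.94 but lay above 0 on array b, and adipocyte genes had a median of 1.99 that came largely from arrays b and e. No single gene passed the limma test after adjustment over 20825 genes, in either direction (smallest adjusted p = 0.617). At an unadjusted p below 0.05 there were 1645 genes, 539 higher and 1106 lower at P90, where chance alone gives 1041 on average. Genes move together within an array, so this count scatters widely. Other ways of signing the same arrays gave from 183 to 4973 genes.

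The arrays did not all run the same way. Across genes, which are not independent replicates, the log2 P90/P30 of array a correlated with that of array e (Pearson r = 0.60) and of array k (r = 0.44), and array e with array k (r = 0.31). Array b correlated negatively with array a (r = -0.31), array e (r = -0.27) and array k (r = -0.19), although its labels give it the same dyes as a and k. Over all probes the value for a and b was -0.303. The labelled direction was kept, since the labels state the dyes of each array and call the comparisons independent; lists whose call changed with array b turned are named as such. Of 9895 genes with the same direction on a, e and k, 6948 (70.3%) had the opposite direction on b. In all, 2942 genes (14.1%) had the same direction on all 4 arrays, 1280 higher and 1662 lower at P90. Chance gives 12.5% for uncorrelated arrays, which these are not.

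**Figure D1:**
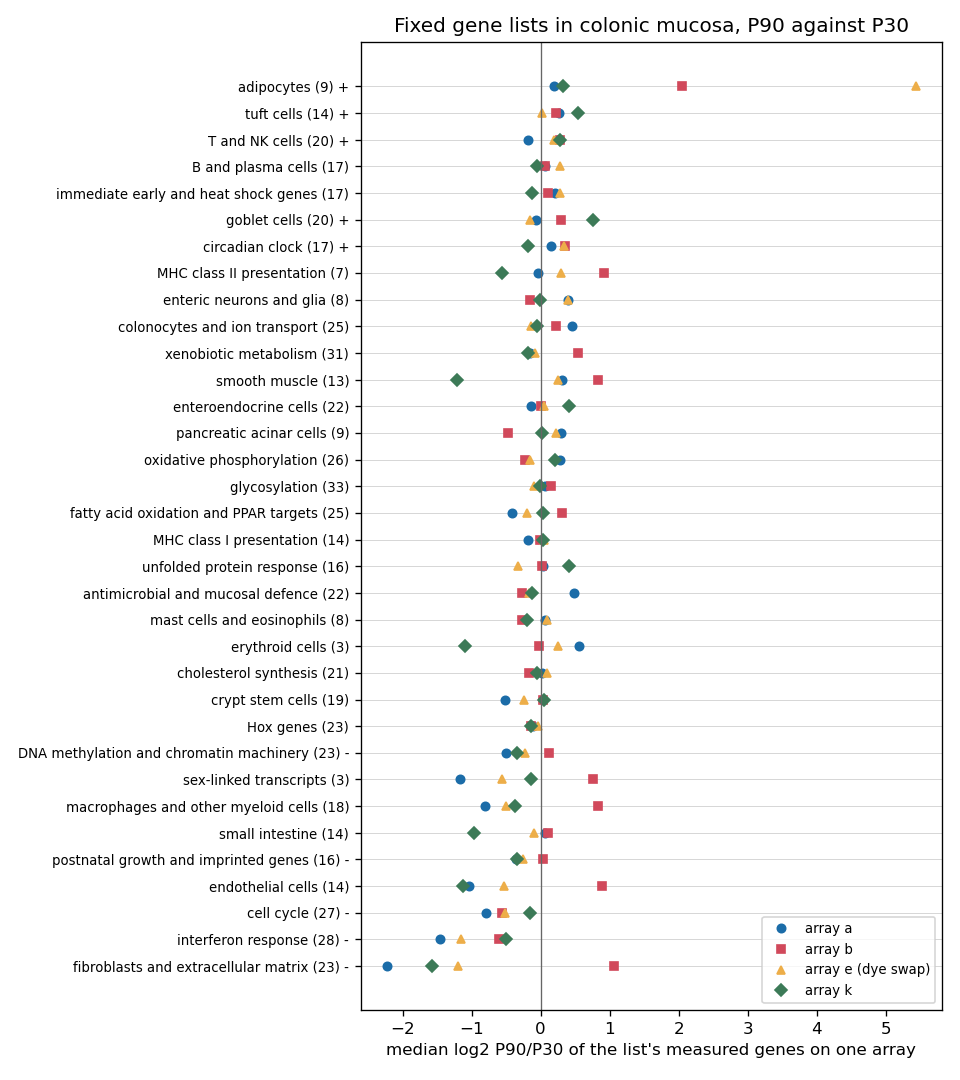
Median log2 P90/P30 of each of the 34 gene lists on each array (x axis), with the number of measured genes in parentheses and + or - after lists that camera with a preset correlation called as higher or lower at P90. The interferon response and cell cycle medians lie below 0 on all 4 arrays, the matrix list lies at 1.06 on array b against -2.22, -1.20 and -1.57 on arrays a, e and k, and the adipocyte list reaches 5.43 on array e.

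Of the 8 genes with a symbol and the smallest p among those higher at P90, 3 belonged to the Cyp3a family. Beside Cyp3a44, Cyp3a16 had a log2 P90/P30 of 2.22 ± 0.73 (SD, n = 4) and Cyp3a41a one of 1.31 ± 0.43. The second probe of Cyp3a44 gave 2.65. These paralogs are near-identical in sequence, so a probe of one may bind transcripts of another and their separate values are uncertain. Cyp3a44 (adjusted p = 0.0219) and Cyp3a16 (adjusted p = 0.0219) passed the limma test when the scanner software's processed signals were used before loess, where their log2 values were 4.38 and 4.43. Both also passed with the deposited log ratios and with the series' value table, and Cyp3a44 passed with the smaller normexp offset. Over all alternatives the adjusted p of Cyp3a44 ran from 0.0148 to 0.99987. Both genes were dim at P30, with mean log2 signals of 6.14 (Cyp3a44) and 6.13 (Cyp3a16) that include the offset of 50. The size of their change depends on the background treatment. For Cyp3a44 it was 3.25 with no background correction, 4.15 with the smaller offset and 5.42 with the value table. Ces2a, a carboxylesterase that hydrolyses drugs and lipids, was at 1.35 ± 0.37. The remaining 4 genes were Ubd, a ubiquitin-like modifier, at 1.47 ± 0.59; Celf3, an RNA-binding protein, at 1.31 ± 0.38; Eva1c at 0.997 ± 0.23; and Cebpa, a transcription factor of differentiating cells, at 0.86 ± 0.21. All 8 were above 0 on all 4 arrays.

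The 8 genes with a symbol and the smallest p among those lower at P90 also had 1 direction on all 4 arrays. Lgr5, the receptor that marks crypt stem cells, had a log2 P90/P30 of -0.90 ± 0.22 (SD, n = 4). Irgm2, an interferon-inducible GTPase, was at -1.31 ± 0.39, and Xaf1, an interferon-inducible gene, at -1.69 ± 0.67. Gatm, the first enzyme of creatine synthesis, was at -1.01 ± 0.28, and Trip13, which acts at meiotic and mitotic checkpoints, at -0.97 ± 0.26. The translation initiation factor gene Eif5 was at -1.11 ± 0.35, Fkbp3 at -1.06 ± 0.34, and Afm at -0.92 ± 0.21. None of these passed the adjusted test.

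Further genes with the same direction on all 4 arrays were picked after the values were seen, as those whose smallest change on any array was largest. Trpv6, the apical calcium channel of intestinal epithelium, had a log2 P90/P30 of -2.87 ± 2.23 (SD, n = 4), and S100g, the calcium-binding protein calbindin-D9k, one of -2.53 ± 1.11, with the P30 channel saturated on arrays e and k, so that its fall is understated there. Rtp4, an interferon-inducible gene, was at -2.31 ± 1.05, Pbp2 at -1.92 ± 1.27, Ppic at -1.82 ± 0.77 and Bex4 at -1.33 ± 0.52. On the higher side, haptoglobin (Hp) was at 2.48 ± 2.03 with 5.50 on array e alone, Cand2 was at 1.17 ± 0.54 and Ccdc92 at 0.89 ± 0.28.

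**Figure D2:**
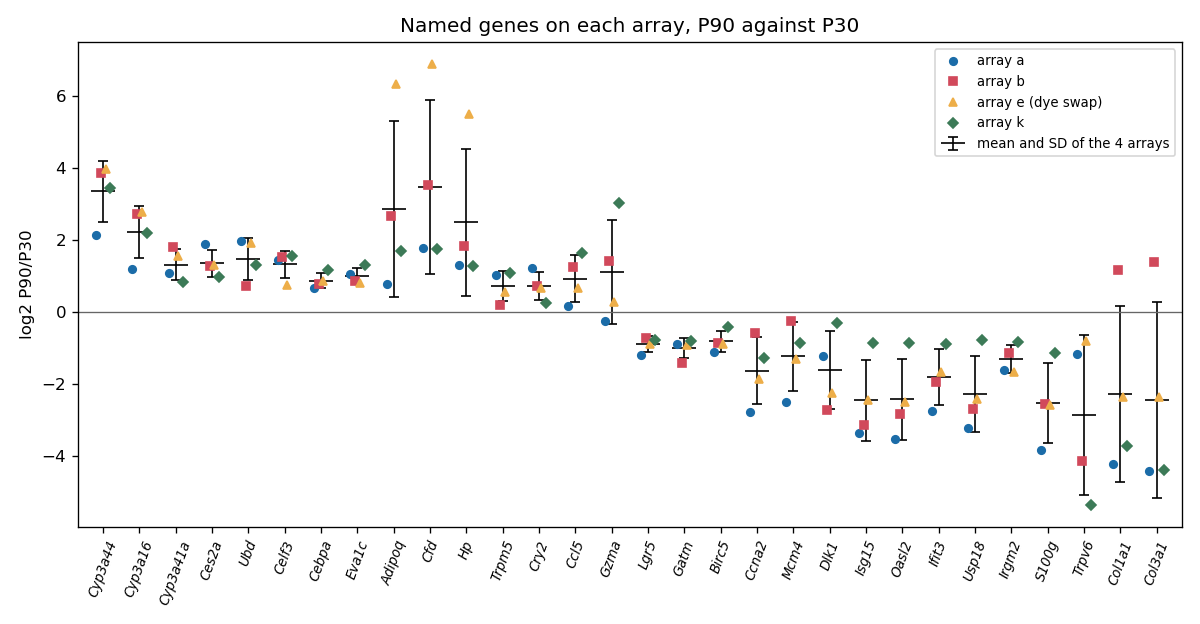
Log2 P90/P30 of 30 named genes on each array (points), with the mean and SD of the 4 arrays (bars), on a linear log2 axis. Cyp3a44 lies between 2.12 and 3.97, Isg15 between -3.36 and -0.87, and Col1a1 at 1.17 on array b against -4.24, -2.36 and -3.73 on arrays a, e and k.

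The interferon response list shifted down by camera with the preset correlation (adjusted p = 1.28e-17; adjusted p = 0.715 with an estimated correlation). Of its 28 measured members, 27 had a mean below 0 and 19 were below 0 on all 4 arrays. None passed over all genes tested, and 20 passed adjusted over the list alone. The array medians were -1.46 on a, -0.60 on b, -1.15 on e and -0.50 on k. Isg15, a ubiquitin-like antiviral protein, was at -2.46 ± 1.13 (SD, n = 4), Oasl2 at -2.43 ± 1.13, the deISGylase gene Usp18 at -2.28 ± 1.06, Oas2 at -1.88 ± 1.27 and Ifit3 at -1.81 ± 0.77. The members of highest intensity were Oas1a at -0.88 ± 0.63 and the transcription factor gene Irf1 at 0.15 ± 0.34. The call was made with each array left out and with array b turned. With an estimated correlation none of the 34 lists was called (1, the tuft list, at an unadjusted p below 0.05). The lists called with the preset correlation all share the adjusted p of 0.715. Their unadjusted camera p ran from 0.0476 (tuft) to 0.282 (matrix), with the interferon list at 0.0525. With fry no list was called either (3 at an unadjusted p below 0.05, smallest adjusted p = 0.509). Lists of antigen presentation genes were not called: MHC class I had a median of -0.072 over 14 genes, with H2-K1 saturated in both channels and H2-D1 in the P30 channel on 3 arrays, and MHC class II one of 0.14 over 7 genes, with Cd74 at 0.26 ± 1.15 and H2-Ab1 at 0.14 ± 0.94. Without array k the MHC class II list was called (median 0.47, adjusted p = 0.00281).

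The cell cycle list shifted down (camera adjusted p = 1.56e-13; adjusted p = 0.715 with an estimated correlation). Of 27 measured members, 26 had a mean below 0, 18 were below 0 on all 4 arrays, none passed over all genes and 12 passed adjusted over the list alone. Cyclin A2 (Ccna2) was at -1.64 ± 0.93 (SD, n = 4), the replication helicase subunit Mcm4 at -1.24 ± 0.95, cyclin B2 (Ccnb2) at -0.84 ± 0.37, Pcna at -0.82 ± 0.46, and survivin (Birc5) at -0.82 ± 0.29. Mcm6 was at -0.56 ± 0.52. With array b turned, the list was not called (adjusted p = 0.125; median -0.22). The crypt stem cell list was not called (median -0.12, 19 genes), with Lgr5 the 1 member past the test adjusted over the list alone; its members of highest intensity, Lrig1 and Prom1, were at 0.057 ± 0.18 and -0.52 ± 0.78.

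The list of fibroblast and extracellular matrix genes shifted down (camera adjusted p = 4.61e-07; adjusted p = 0.715 with an estimated correlation), with all 23 measured members below 0 on average and none in 1 direction on all 4 arrays. Its estimated inter-gene correlation was 0.93. The collagen genes Col3a1 and Col1a1 were at -2.45 ± 2.73 (SD, n = 4) and -2.29 ± 2.44, Col1a2 at -2.11 ± 2.53 and periostin (Postn) at -1.92 ± 2.83, each above 0 on array b and below 0 on a, e and k. Other probes of Col1a1 gave -1.01 and -0.18, and that of Col3a1 -0.18. The list was not called with the sign of array e unturned, which reads that array against its labelled dyes. Endothelial genes (median -0.47, 14 genes) and myeloid genes (median -0.28, 18 genes) were split between arrays in the same way and were not called. Their medians on array b were 0.89 and 0.83. The estimated inter-gene correlations of these 2 lists were 0.89 and 0.51, far above the preset 0.01 used for the calls given below. Plvap and Ramp2 of the endothelial list were at -0.58 ± 1.43 and -0.63 ± 1.40, and the macrophage gene C1qc at -0.71 ± 1.36 and Cd14 at 0.19 ± 0.62. Both lists were called without array b (endothelial median -1.05, adjusted p = 3.72e-06; myeloid median -0.58, adjusted p = 0.000238), with array b turned, with arrays b and e left out and with array weights, and the endothelial list also with processed signals, the smaller offset, the deposited log ratios and the series' value table. Smooth muscle genes had a median of -0.0031 over 13 genes, with -1.22 on array k and 0.83 on array b, and were called without array k (median 0.44, adjusted p = 2.40e-06); Acta2 was at -0.0031 ± 0.69 and Tagln at 0.16 ± 0.95.

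Adipocyte genes shifted up (camera adjusted p = 6.28e-06; adjusted p = 0.715 with an estimated correlation). All 9 measured members had a mean above 0 and 5 were above 0 on all 4 arrays. The array medians were 0.19 on a, 2.04 on b, 5.43 on e and 0.33 on k, so the spread between arrays exceeded the mean. Adipsin (Cfd) was at 3.47 ± 2.41 (SD, n = 4), adiponectin (Adipoq) at 2.85 ± 2.43, the lipid droplet gene Plin4 at 2.48 ± 2.48 and Car3 at 1.99 ± 2.54. Fabp4 and Cidec were at 1.30 ± 2.53 and 0.77 ± 1.74. The list was not called with arrays b and e both left out, with array b turned, with the sign of array e unturned or with a variance trend.

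Tuft cell genes shifted up (camera adjusted p = 0.000104; adjusted p = 0.715 with an estimated correlation), with a median of 0.36 and 13 of 14 members above 0, 5 of them on all 4 arrays. The taste-transduction channel Trpm5 was at 0.71 ± 0.42 (SD, n = 4), the leukotriene enzyme Alox5 at 0.66 ± 0.53 and Gfi1b at 0.54 ± 0.44, while Ptgs1 was at 0.10 ± 0.97. The array medians were 0.27 on a, 0.22 on b, 0.020 on the dye swap e and 0.54 on k. With array b turned the tuft list was not called. T and NK cell genes shifted up (adjusted p = 0.00199; adjusted p = 0.715 with an estimated correlation), with a median of 0.17 and 18 of 20 members above 0. The granzyme gene Gzma was at 1.11 ± 1.45, from -0.25 on array a to 3.01 on array k, and the chemokine gene Ccl5 at 0.92 ± 0.65; Cd8a was at 0.47 ± 0.67, Cd3g at 0.39 ± 0.52 and Thy1 at -0.19 ± 0.77. The T and NK list was not called without array b (median 0.16, adjusted p = 0.0860), with array b turned or with arrays b and e left out. B and plasma cell genes just missed the threshold (adjusted p = 0.0510, median 0.049, 17 genes), with Jchain at 0.49 ± 2.35 and Pou2af1 at 0.41 ± 1.44. That list was called in 9 of 21 alternatives, without array a (adjusted p = 0.0432) and without array k (adjusted p = 0.000725) among them.

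Goblet cell genes shifted up (camera adjusted p = 0.0106; adjusted p = 0.715 with an estimated correlation), with a median of 0.20 and 15 of 20 members above 0. The members of highest intensity, Zg16 and Clca1, were saturated in both channels on every array and give no ratio; the list was not called with saturated probes left out, without array b (median 0.20, adjusted p = 0.0860), without array k (median 0.049, adjusted p = 0.556), with array b turned, with median centring or with a dye term. Fcgbp, saturated in the P90 channel on every array and in the P30 channel on 3 of them, gives no ratio either. Creb3l1 was at 0.58 ± 0.77 (SD, n = 4) and the calpain gene Capn9 at 0.57 ± 0.56. The array medians of the goblet list were -0.065 on a, 0.29 on b, -0.16 on e and 0.76 on k. Circadian clock genes shifted up (adjusted p = 0.0145; adjusted p = 0.715 with an estimated correlation; median 0.090, 12 of 17 members above 0). The repressor gene Cry2 was at 0.71 ± 0.40, Tef at 0.39 ± 0.26 and Nfil3 at 0.28 ± 0.69; the output genes Dbp and Bhlhe40 were at 0.026 ± 0.45 and -0.11 ± 0.58. The second probe of Cry2 was at -0.015. The clock list was not called without array b (median 0.052, adjusted p = 0.252), without array e (median 0.096, adjusted p = 0.0890) or without both, with the sign of either turned, with median centring or with array weights.

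Genes of DNA methylation and chromatin shifted down (camera adjusted p = 0.0106; adjusted p = 0.715 with an estimated correlation), with a median of -0.23 and 19 of 23 members below 0. The polycomb genes Eed and Ezh2 were at -0.73 ± 0.72 (SD, n = 4) and -0.63 ± 0.67, the cytidine deaminase gene Apobec1 at -0.73 ± 0.65 and the DNA glycosylase gene Tdg at -0.50 ± 0.28; Mat2a was at 0.21 ± 0.49 and Mbd1 at -0.0025 ± 0.39. The second probe of Apobec1 was at -0.018. The list was not called without array k (median -0.19, adjusted p = 0.0585) or with the sign of array e unturned. Postnatal growth and imprinted genes shifted down (adjusted p = 0.0271; adjusted p = 0.715 with an estimated correlation; median -0.22, 12 of 16 members below 0). Dlk1, an imprinted growth regulator, was at -1.63 ± 1.08, the imprinted adaptor gene Grb10 at -1.13 ± 0.43, Hmga2 at -0.90 ± 0.73 and Sgce at -0.63 ± 1.31, while Gnas and Igf2r were at -0.082 ± 0.10 and -0.14 ± 0.43. Grb10 passed adjusted over the list alone, but its other probes gave -0.063 and 0.11. This list was not called without array e (median -0.21, adjusted p = 0.0597), without array k (median -0.23, adjusted p = 0.0589), with the sign of array b or e turned, with the strict filter, with the mean of a gene's probes or with a variance trend.

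The xenobiotic metabolism list was not called (adjusted p = 0.104, median 0.042, 31 genes), with 16 members above 0 and 15 below; it was called as higher without array a (median 0.089, adjusted p = 0.00220) and without array k (median 0.10, adjusted p = 0.0290), and with the deposited log ratios, the value table and saturated probes left out. Ces2a, Cyp3a11 and Gsta3 passed adjusted over the list alone. Cyp3a11, the main Cyp3a enzyme of mouse liver, was at 1.71 ± 0.95 (SD, n = 4) and the glutathione transferase gene Gsta3 at -0.88 ± 0.43, whereas Cyp3a13 was at -0.14 ± 0.71 and Cyp3a25 at 0.74 ± 1.19. Gstm1 was at -0.20 ± 0.46, and Gsto1 was saturated in the P30 channel on 3 arrays. Cholesterol synthesis genes had a median of -0.20 over 21 genes and were called with median centring alone, with Stard4 (-0.82 ± 0.28) past the test adjusted over the list alone and 2 other probes of Stard4 at 0.078 and 0.11. In the mast cell and eosinophil list (median -0.013, 8 genes), the mast cell proteases Mcpt1 (-0.57 ± 0.26) and Mcpt4 (-0.58 ± 0.25) passed adjusted over the list alone, and Cma1 was at -0.014 ± 1.31.

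The remaining lists of epithelial and metabolic genes were not called in the main fit. Medians were 0.096 for colonocytes and ion transport (25 genes), 0.019 for enteroendocrine cells (22 genes), 0.057 for mucosal defence (22 genes), 0.018 for fatty acid oxidation and PPAR targets (25 genes), 0.018 for oxidative phosphorylation (26 genes), 0.0029 for glycosylation (33 genes), 0.055 for the unfolded protein response (16 genes), 0.067 for immediate early and heat shock genes (17 genes) and -0.15 for Hox genes (23 genes). Leaving out array k gave calls for colonocytes (median 0.36, adjusted p = 0.00525) and for immediate early and heat shock genes (median 0.083, adjusted p = 0.0286), and leaving out array a one for enteroendocrine cells (median 0.12, adjusted p = 0.0176), which were also called with arrays b and e left out. Oxidative phosphorylation was called as higher with the deposited log ratios (median 0.18), the value table, the sign of array e unturned, and arrays b and e left out. Colonocytes and immediate early and heat shock genes were also called with the deposited log ratios and the value table, the latter list with a dye term too, and the unfolded protein response with the sign of array e unturned. Guca2a, a guanylin precursor, and the respiratory chain gene Cox4i1 were saturated in both channels on every array, and Vil1, Atp5b and Sprr2a1 in the P30 channel, so no ratio is given for them. Of the genes given a value, Mat2a, Acadvl and Fabp2 were saturated in the P30 channel on arrays a and k, so that their ratios there are upper limits, and Cfd, Fabp4, Pyy, Sct and Hspa8 in 1 channel on 1 array and Gstm1 in each channel on 1, which makes those values uncertain. Pyy and Sct of the enteroendocrine list were at 0.061 ± 0.66 and 0.15 ± 0.84 (SD, n = 4). Saa2 was saturated on 3 arrays in each channel and is given no ratio. Acadvl of fatty acid oxidation was at 0.18 ± 0.21, the glycosyltransferase genes B4galt1 and St6galnac6 at 0.17 ± 0.82 and 0.24 ± 0.38, the endoplasmic reticulum genes Creld2 and Pdia6 at 0.11 ± 0.48 and -0.082 ± 0.53, and the chaperone genes Dnajb1 and Hspa8 at 0.29 ± 0.53 and 0.014 ± 0.35. The Hox genes of highest intensity, Hoxb13 and Hoxb7, were at 0.25 ± 1.90 and -0.56 ± 1.55. For 6 of the 34 lists, none of them called, the median, the mean and the direction of camera differed in sign, so no direction is given for smooth muscle, glycosylation, mucosal defence, the unfolded protein response, MHC class I or fatty acid oxidation. Another probe lay on the other side of 0 for Acta2, B4galt1, Gnas, Gstm1, Mbd1 and Thy1.

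Lists for tissue that could adhere to the mucosa or lie next to it were also measured. Small intestinal genes had a median of -0.45 over 14 genes, with -0.96 on array k; Fabp2 and Slc10a2 were at -0.60 ± 0.73 and -0.61 ± 1.09 (SD, n = 4). Genes of enteric neurons and glia had a median of 0.15 over 8 genes, with S100b at 0.22 ± 0.52 and Tubb3 at -0.0021 ± 1.07, pancreatic acinar genes one of 0.016 over 9 genes, with Cela1 at 0.56 ± 1.23 and Clps at 0.29 ± 0.48, and erythroid genes one of -0.00097 over 3 genes, with Alas2 at 0.00073 ± 0.80 and Hba-a1 at -0.34 ± 1.17. None of these was called; the small intestinal list was called without array a (median -0.27, adjusted p = 0.00907), and the neuronal list without array k (median 0.25, adjusted p = 0.0290), with median centring, with a dye term and with the processed signals, deposited log ratios or value table. Xist, the transcript of the inactive X chromosome, was not well above background in any channel of any array. The Y-linked transcripts Eif2s3y, Kdm5d and Ddx3y were measured at -0.58 ± 1.001, -0.28 ± 0.80 and 0.13 ± 0.44, and their list had a median of -0.28.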

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

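Of 184 sets of 4 array values examined (named genes and list medians), 8 had 1 array far from the other 3, where about 1 in 20, or 9.2, is expected by chance. The tests on array b, on immune and myeloid cells and on dye bias in the adipocyte list were chosen only after the result was seen; those on second probes and on the dye term were fixed before their results were seen. So was that on a second adipocyte list, except that Cebpa was taken off the list later.

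Array e stood apart for Hp at 5.50, against 1.27 to 1.83 on the other arrays, and for Celf3 at 0.74, against 1.43 to 1.54. Array k stood apart for Apobec1 at -1.70 (others -0.50 to -0.32), Cand2 at 1.97 (others 0.82 to 1.01) and Mbd1 at -0.58 (others 0.12 to 0.23). Array b stood apart for Plvap at 1.54 (others -1.52 to -1.002), Ptgs1 at 1.54 (others -0.61 to -0.26) and the median of the xenobiotic metabolism list at 0.54 (others -0.18 to -0.088).

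Array b ran against arrays a, e and k. A different share of stroma with smooth muscle included is argued against by arrays a and e alone. There smooth muscle genes lay 2.53 and 1.45 above matrix genes, with medians of 0.31 and 0.25 against -2.22 and -1.20. The permutation p-values were 1e-05, the smallest that 100000 resamples of genes can give, and 0.00012. They treat genes as independent, although matrix genes had an estimated correlation of 0.93, and do not measure the spread between samples. The matrix, endothelial and myeloid medians had the same sign as each other on each array. Endothelial and myeloid medians were -1.04 and -0.81 on a, -0.52 and -0.50 on e, and -1.13 and -0.37 on k. A different share of stroma without smooth muscle therefore stays open. More stroma in the P90 tissue of array b alone may contribute: there the matrix, endothelial, myeloid and smooth muscle medians lay between 0.83 and 1.06, with smooth muscle minus matrix at -0.23 (permutation p = 0.301). On array k the same lists lay between -1.57 and -0.37. Signal that depends on the probe may also contribute. The difference between 2 probes of 1 gene, over 4629 genes, correlated at -0.56 between arrays b and e and at -0.33 between b and a. Between b and k it was -0.067, and among the other arrays 0.42 (a and e), 0.50 (a and k) and 0.23 (e and k). A real change read unequally by 2 probes could add to such values. Over 645 genes whose 2-probe mean stayed within 0.3 on every array they were -0.57 (b and e), -0.26 (b and a) and -0.025 (b and k). Among the other arrays they lay between 0.19 and 0.40. A dye bias of probes would put b and e apart but not b and a. Reversed dye labels on array b would also turn the sign of its probe differences, so these values do not separate the 2 explanations. Reversed dye labels on array b cannot be told apart from a real difference of that pair. Turning the array aligned 3 of the 4 lists that moved beyond 0.3 on a, e and k. Those 3, the matrix, endothelial and myeloid lists, moved together on every array and are not separate lines of support. Turning set the interferon list against the other arrays at 0.60. The cell cycle list, at -0.56 on b, would also be set against them, but missed the bound through array k at -0.15. Of 183 genes beyond 1 in the same direction on a, e and k, 55 were beyond 1 the opposite way on b and 9 the same way, Cyp3a44 among the latter.

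The median of the interferon response list lay below 0 on all 4 arrays, as did 19 of its 28 members, none past the test. Dye bias is argued against, since the median stayed at -0.97 with a dye term. Fewer immune cells as a whole are also argued against, since the T and NK list lay 1.12 above the interferon list, with an SD over arrays of 0.28. The permutation p for that difference, 0.00019, and the next one treat genes as independent and do not measure the spread between arrays. Fewer myeloid cells stay open: the myeloid list lay 0.66 above the interferon list (permutation p = 0.00033), but this difference ran from 0.13 on array k to 1.43 on array b (SD 0.54). Probe-dependent signal stays open. The 14 second probes of 9 of these genes had a median of -0.503, with 12 of 14 below 0. Their medians lay below 0 on all 4 arrays (-1.05, -0.24, -0.72 and -0.085). This met the bound set beforehand, a median below -0.5 and below 0 on all 4 arrays, but by far less than the standard error of 0.15. Passing by a margin of that error was not part of the bound. A change with age, which the design names, stays open and was not tested apart from other differences between the paired RNAs.

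Adipocyte genes were far higher at P90 on array e. Dye bias of the swapped array is argued against by array b, which as labelled has the other orientation and a median of 2.04. That holds only if the dye labels of array b are right, since turning the array would make its median negative. Arrays a and k, with the same labelled orientation as b, lay at only 0.19 and 0.33. RNA from attached fat in the P90 tissue may be the source: a second list of adipocyte transcripts, with 10 of 14 measured and none in the first list, had a median of 1.72 on array e, against 0.77 on b, 0.11 on a and -0.17 on k. With Cebpa kept the median on array e was 1.71. On array e the fat-derived transcripts Cfd and Adipoq were at 6.87 and 6.32 and Cyp2e1 of the second list at 4.71, while Cd36, Lpl and Cav1 of that list are also made by other cells of the mucosa. An age difference in the fat of the mucosa stays open and was not tested.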

How the results depend on the processing

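The alternatives with array b turned, with arrays b and e both left out and with saturated probes left out, and the counts over other signs of the arrays, were chosen after seeing the data. The number of genes past the limma test was 0 in both directions under the other alternatives, looser and stricter thresholds included. The exceptions were all higher at P90. There were 2 genes with processed signals, 2 with deposited log ratios, 2 with the series' value table and 1 with the smaller offset. These were Cyp3a44 and Cyp3a16, with Cyp3a44 alone at the smaller offset. Both were dim at P30, and their ratios were larger in each of these settings than in the main fit. Whether this alone made them pass was not tested. The smallest adjusted p ranged from 0.0148 to 0.99987. Median centring in place of loess moved the median of all genes from -0.020 to -0.21 and the share of higher genes among those at an unadjusted p below 0.05 from 32.8% to 2.42%, so changes there are relative to that shift. Turning array b raised the genes at an unadjusted p below 0.05 from 1645 to 4973, and leaving it out to 4654.

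Lists shifted up numbered 5 and lists shifted down 5. Lists shifted up were 10 with deposited log ratios, 10 with the series' value table and 0 with array b turned, and 2 to 11 with 1 array left out (2 without array b, 8 without array a, 11 without array k). Lists shifted down were 2 with the sign of array e unturned, and 3 to 7 with 1 array left out (3 without array k, 7 without array b). Both counts were 0 with an estimated correlation and 0 with fry; the estimated correlation is far above the preset one for most lists (median 0.215). Each in its main direction, the interferon list was called in 21 of 21 alternatives that keep the preset correlation (medians -1.31 to -0.38), the cell cycle and tuft lists in 20, the matrix list in 20, the chromatin list in 19, T and NK cells in 18, adipocytes in 17, goblet cells in 15, and the clock and imprinted lists in 14. Among the 21, those with array e unturned or array b turned go against the labelled dyes.

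A gene's value counts as reversed when it changed sign and moved by more than its SD over arrays. Changes of sign within the SD are not listed, nor are moves beyond the SD without a change of sign. The latter befell 11 of 133 named genes with processed signals, 14 with median centring, 28 with array b turned and 33 with the sign of array e unturned. With the sign of array e unturned the adipocyte list reversed to -0.58, and so did Adipoq (-0.31), Car3 (-0.73), Cyp2e1 (-0.58), G0s2 (-0.32), Hp (-0.27), Nnat (-0.46), Plin4 (-0.57) and Thrsp (-0.34), by construction. Median centring reversed Acadvl (-0.11), Lrig1 (-0.31) and Vdr (-0.19). Grb10 reversed to 0.11 with the strict filter and Gnas to 0.017 with the mean of its probes, where other probes entered. Oas1a went to 0.0076 with array b turned.

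Of the 8 ways of signing the 4 arrays, all 8 gave as many genes past the test (0 as labelled, highest other 0), 2 gave as many at an unadjusted p below 0.05 (1645, highest other 4973, with array b turned) and 4 gave as many lists (10, highest other 16). With 8 ways no share can fall under 0.05. Arrays a and k had the fewest P90 spots well above background (55.6% and 57.3%), which limits ratios of dim genes there.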

Other observations

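The test of the calcium uptake genes was chosen after Trpv6 and S100g were seen among the genes lower on all 4 arrays; its bounds were set before the other members were looked at. The Cyp3a genes and Ubd were singled out after their values were seen, with no test.

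Trpv6 and S100g, the channel and the cytosolic buffer of calcium uptake in the intestine, had log2 P90/P30 values far below 0 on single arrays, with Trpv6 at -5.36 on array k and -4.14 on array b, and S100g at -3.84 on array a. One hypothesis is that calcium uptake genes as a group were lower at P90. The 4 measured members, of 7 listed beside these, had a median of 0.019, from -0.70 for the calcium pump gene Atp2b1 to 0.13 for Cldn2, with the vitamin D receptor gene Vdr at 0.12 and Cldn15 at -0.084. The log2 P90/P30 of Cldn2 turned to -0.27 with median centring. The median of the 4 members passed the bound set beforehand against the hypothesis. That bound held no margin for the spread of the members (SD 0.39), which leaves open whether the group moves with Trpv6 and S100g.

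Of the Cyp3a family, Cyp3a11, Cyp3a16, Cyp3a41a and Cyp3a44 were above 0 on all 4 arrays and under each scaling tried. The log2 P90/P30 of Cyp3a13 ran from -0.82 on array k to 0.84 on array b, with a mean between -0.47 under median centring and 0.0055 with the deposited log ratios, and that of Cyp3a25 from -0.36 on array k to 2.23 on array b, so neither is given a direction. The difference between these genes was not tested.

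Ubd, an interferon-inducible gene outside the fixed lists, was above 0 on all 4 arrays, from 0.71 on array b to 1.95 on array a, while the median of the interferon response list was below 0 on each of them.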
